A study of Homo sapiens with 3 samples.

How the data were processed

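Total RNA of DLD1 cells was labelled with Cy3 and hybridised to Agilent 1-colour expression arrays, 1 array for each of the control shRNA, GATA6 shRNA and LGR5 shRNA groups, per the labels. Per the file headers, the scans were read with Agilent Feature Extraction 10.5.1.1, and the probe positions are those of hg18. The deposited scanner files give each spot's intensity on a linear scale: a processed signal that is background-subtracted and detrended but not normalized between arrays, and the mean signal and local background behind it. The deposited files also hold flags for spots well above background, saturated or outlying. The authors also deposited a table of log2 values whose making is not given in the sources used here. Compared with the scanner files, more than 99.9% of its values lay within 0.02 of the log2 processed signal minus the array's 75th percentile, centred on each probe's median over the 3 arrays, and each column's median was 0. It was used as an alternative, with higher meaning brighter.

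Each array had 45015 spots, of which 43376 belonged to 41000 gene probes. Control spots were left out, as were spots with an outlier flag (59, 67 and 73 on the control, GATA6 shRNA and LGR5 shRNA arrays). No gene spot was saturated. The log2 processed signal was reduced by the 75th percentile of its array, which was 1266, 1383 and 1743, and the spots of a probe were averaged. Probes were named through a RefSeq table (GRCh38.p14, used for names only) by accession (23958 probes), by symbol (2755) or by an older symbol (1032), and 13255 probes stayed unnamed and out of the gene counts. The 17843 named genes, 7237 of them with several probes, were each represented by the probe with the highest mean signal. Other measured probes had the same sign as this probe in 69.5%, 65.7% and 72.7% of cases for GATA6 shRNA minus control, LGR5 shRNA minus control and LGR5 minus GATA6 shRNA. Where this probe was at least 2-fold higher, 31.3%, 31.7% and 42.0% of the other measured probes were also at least 2-fold higher, and where it was at least 2-fold lower, 32.5%, 28.8% and 37.8% were also at least 2-fold lower.

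A gene was measured in a comparison when its probe was well above background on both arrays, and higher or lower meant at least 2-fold. Where a gene was well above background on 1 array and on no probe of the other, a lower bound was given: the brighter signal over the higher of the dim probe's own signal and the lowest signal of any probe well above background on that array. Of 264 probes printed 10 times, the 227 well above background on all arrays gave the spot error, with the SD pooled over the 60 nearest in signal. Probes dimmer than these took the SD of the dimmest 60, so the error printed for very dim probes may be too small. Over the 227, the pooled SD of a single spot was 0.12, 0.10 and 0.09 log2 units on the control, GATA6 shRNA and LGR5 shRNA arrays. With no replicates, no test was made. The median of each gene list was given as a percentile among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. The shift is the median minus that of the random lists, and a percentile in either outer tail of 2.5% counted as outside the range. Before the data were examined, the genes to be named were fixed as GATA6, LGR5 and REG4, the 10 highest and 10 lowest genes per comparison that had a gene symbol, were at least 2-fold different and whose other measured probes had the same direction, up to 4 members per list that were at least 2-fold different, and the 5 largest bounds per direction. Some genes that this rule names are not reported here.

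The alternatives were normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), median, quantile and spike-in scaling (8 spike-in probes), the deposited log2 table, no filter on dim probes, only genes above the median signal, the mean over probes, subtraction of the local median in windows of 31 rows and 31 columns, outlier spots kept, and thresholds of 1.5-fold and 3-fold. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The steps were tested on simulated arrays of 14320 genes with the spot error and 200 changed genes. For GATA6 shRNA minus control, 100% of genes changed 3-fold, 5-fold or 10-fold passed the 2-fold threshold, and 0 of 14120 unchanged genes did. In that comparison 2% of random lists fell outside the range, for LGR5 shRNA minus control 8% and for LGR5 minus GATA6 shRNA 4%. These simulations hold spot error only, and their lists were random draws of unchanged genes with independent error. The share outside the range is then set by the design, and it does not apply to lists whose genes vary together. Each of the 23 lists with a value was examined in all 3 comparisons, and 3 further lists (short-lived, ERK pathway output and abundant blood cell transcripts) were written after the data were seen.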

Results

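Gene expression was measured in DLD1, a human colorectal adenocarcinoma cell line, after infection with lentivirus that expressed an shRNA, a short hairpin RNA that lowers the level of its target transcript. Of the 3 arrays, 1 came from cells labelled control shRNA, 1 from cells with an shRNA against GATA6 and 1 from cells with an shRNA against LGR5. The title of the control sample calls it shEmpty, so the labels do not settle whether its virus expressed an shRNA. Differences from the control that both other arrays share therefore cannot be assigned to the targeted genes. GATA6 is a zinc finger transcription factor of endoderm and gut epithelium, and LGR5 is a receptor for R-spondins that marks intestinal stem cells. The study asked which transcripts differ when either gene is suppressed in colorectal cancer cells. Each 1-colour array carried 41000 probes, of which 76.9% were well above background on the control array, 75.2% on the GATA6 shRNA array and 75.8% on the LGR5 shRNA array. With 1 array per group there were no replicates, so no p-value could be given, and the number of arrays limits the precision of each value below. The error printed is the SD expected from the spread of repeated spots on the arrays, which leaves out variation between cultures, labelling reactions and hybridisations.

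The level of the targeted genes was read first. GATA6 had a signal of 5986 on the control array, 1698 on the GATA6 shRNA array and 8214 on the LGR5 shRNA array. After scaling, GATA6 was 3.85-fold lower on the GATA6 shRNA array than on the control array, a log2 difference of -1.95 ± 0.09 (spot SD). Between the LGR5 shRNA and control arrays its log2 difference was -0.005 ± 0.078. With spike-in scaling these differences were -1.73 and 0.65. The only GATA6 probe lies on chromosome 18 at 18035791 to 18035850 (hg18). The LGR5 probe, on chromosome 12 at 70264592 to 70264651 (hg18), was dim on every array, with signals of 15.4 on the control array, 6.71 on the GATA6 shRNA array and 9.498 on the LGR5 shRNA array. It was well above background on the control array alone. Dim probes brighter on the control array than on both others were in excess, as given below. A lower LGR5 level cannot be told apart from that pattern, so these arrays do not establish knockdown of LGR5. With 75th percentile scaling LGR5 was at least 2.23-fold lower on the LGR5 shRNA array and at least 1.93-fold lower on the GATA6 shRNA array than on the control array. As log2 bounds these were -1.15 and -0.95, each with a spot SD of 0.26. The bound for the LGR5 shRNA array equals the observed difference, because the probe's own signal lay above the lowest signal well above background there. These bounds depended on the setting: for the LGR5 shRNA array the bound was at least 1.41-fold with spike-in scaling, 1.53-fold with normexp background correction and 1.61-fold after quantile normalization. For the GATA6 shRNA array it was at least 1.24-fold with normexp. Which part of either transcript the probes match was not determined here.

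REG4, a secreted lectin of the regenerating family, was 11.7-fold lower on the GATA6 shRNA array than on the control array, a log2 difference of -3.55 ± 0.11. On the LGR5 shRNA array REG4 was 2.38-fold lower than on the control array, a log2 difference of -1.25 ± 0.09, and with spike-in scaling this difference was -0.60, less than 2-fold. Its signals were 1669 on the control array, 156 on the GATA6 shRNA array and 964 on the LGR5 shRNA array, from a probe on chromosome 1 at 120138663 to 120138722 (hg18). A second REG4 probe gave log2 differences of -3.32 and -1.08 for the same comparisons.

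**Figure D1:**
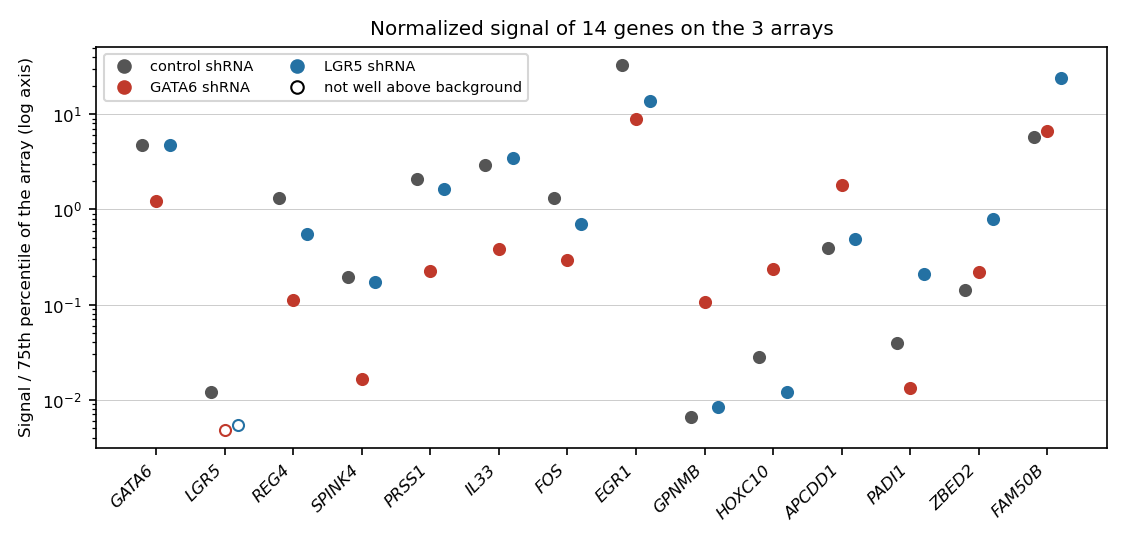
Normalized signal (signal divided by the 75th percentile of its array, log axis) of 14 genes on the control shRNA (grey), GATA6 shRNA (red) and LGR5 shRNA (blue) arrays, 1 point per array; open points were not well above background. GATA6, REG4, SPINK4, PRSS1 and IL33 were lowest on the GATA6 shRNA array, and LGR5 lay near background throughout.

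The comparison of the GATA6 shRNA and control arrays asked which transcripts differ when GATA6 is suppressed. Among 14431 genes measured on both arrays, 309 were at least 2-fold higher and 262 at least 2-fold lower on the GATA6 shRNA array. SPINK4, a protease inhibitor of goblet cells, was 11.9-fold lower, with a log2 difference of -3.57 ± 0.18. The probe named for PRSS1, a trypsinogen, was 9.38-fold lower, and because trypsinogen genes are close copies its assignment among family members is uncertain. IL33, a nuclear cytokine of epithelial cells, was 7.62-fold lower and was bright, with signals of 3672 on the control array and 527 on the GATA6 shRNA array. The other genes among the 10 lowest were ACKR5, HLA-DQB1, HBD, NXNL1, ADAMTS15 and IGKV1-5, which were 8.77 to 11.7-fold lower. All 6 of these were dim on both shRNA arrays and brighter on the control array than on either of them, and 2 other HLA-DQB1 probes gave log2 differences of -0.12 and -0.10. The highest gene was GPNMB, a transmembrane glycoprotein, which was 16.1-fold higher with a log2 difference of 4.01 ± 0.23. Its signal on the control array was 8.35, near the lowest signal well above background there, 7.91. Another GPNMB probe was not well above background on any array. HOXC10, a homeobox transcription factor, was 8.34-fold higher, although its second probe gave a log2 difference of only 0.40. IL1B, an inflammatory cytokine, was 7.99-fold higher, with signals of 15.9 and 139. MYH7B, MAGI2, ZFTRAF1, EPB41L3, PDZK1 and VTCN1 were 5.56 to 7.56-fold higher, and MKI67, which encodes the proliferation marker Ki-67, was 5.96-fold higher.

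Of 24 gene lists fixed before the data were examined, 23 had enough measured members for a value (the REG family list had 1), and each median was set against random lists matched on signal, a contrast that a shift of all genes leaves in place. Immediate-early genes, transcription factors and phosphatases that respond within minutes to growth stimuli, had the largest shift, -0.63, with 9 of 26 measured members at least 2-fold lower and none higher. FOS was 4.47-fold lower, EGR1 3.67-fold, EGR3 3.45-fold and IER3 2.60-fold. Short-lived transcripts outside this list, a list written after the data were seen, were shifted by -0.50 in the same comparison. DNA replication and S phase genes were shifted by 0.43 and mitosis genes by 0.39, with E2F1 2.59-fold and GINS2 2.35-fold higher. Wnt/beta-catenin target genes were shifted by 0.25, and APCDD1 was 4.63-fold, ETS2 2.27-fold and NKD1 2.01-fold higher. Intestinal stem cell markers, which share several genes with the Wnt list, were shifted by 0.31, with none of 18 measured members 2-fold different. Members of this list that were not measured on both arrays went both ways. ALDH1A1 was at least 7.05-fold higher as a bound, given below. LGR5, from its dim probe, was at least 1.93-fold lower as a bound. Enterocyte differentiation markers were shifted by -0.31, with LGALS4 4.51-fold and CDH17 2.02-fold lower, and this shift lay inside the range of random lists when only genes above the median signal were kept. Gut endoderm transcription factors, among them GATA6 itself, were shifted by -0.29. Smaller negative shifts were found for BMP and TGF-beta response genes (-0.21), epithelial genes (-0.14), unfolded protein and amino acid stress response genes (-0.23) and cholesterol and fatty acid synthesis genes (-0.15). BMP7 was 2.83-fold higher by a dim probe, while another BMP7 probe gave a log2 difference of -0.21. The remaining 12 lists, among them secretory lineage, interferon, p53, hypoxia and ribosomal protein genes, lay inside the range, with shifts between -0.18 and 0.10. Markers of fibroblasts, endothelial and blood cells were also inside it, at -0.18.

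A further 48 genes were at least 2-fold higher as a lower bound, because they were well above background on the GATA6 shRNA array and on no probe of the control array. The largest bounds were at least 21.3-fold for FNDC9, at least 14.5-fold for CREB5, at least 10.1-fold for SLC26A7, at least 7.05-fold for ALDH1A1 and at least 6.39-fold for HSPA12B. Other probes of CREB5 and SLC26A7, and of KRT77 named next, were not well above background on any array. In the other direction 95 genes had such a bound, the largest being at least 53.5-fold for TBX21, at least 39.8-fold for KRT77, at least 13.7-fold for WDR64, at least 13.1-fold for GPR174 and at least 12.6-fold for RAG2. The control array held more such signals than the others: 216 probes were at least 4-fold above both other arrays on the control array, against 72 on the GATA6 shRNA array and 40 on the LGR5 shRNA array. The median signal of the 216 probes on the control array was 27.2. The split of 309 higher and 262 lower genes became 529 and 146 with spike-in scaling, which moved the median of all genes to 0.22. After normexp background correction 7 named genes were less than 2-fold different: EPB41L3 (0.66, from 2.58), BMP7 (0.31, from 1.4998), TNF (0.21, from 1.25), NKD1 (0.56, from 1.01), CSF2 (-0.91, from -1.33), VWF (0.92, from 1.09) and CDH17, which hardly moved (-0.98, from -1.01). Of 2 other ETS2 probes, 1 gave 1.25 and 1 gave 0.92. With a signal over 100 on both arrays, a filter chosen after seeing the data, 130 genes were higher and 129 lower.

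**Figure D2:**
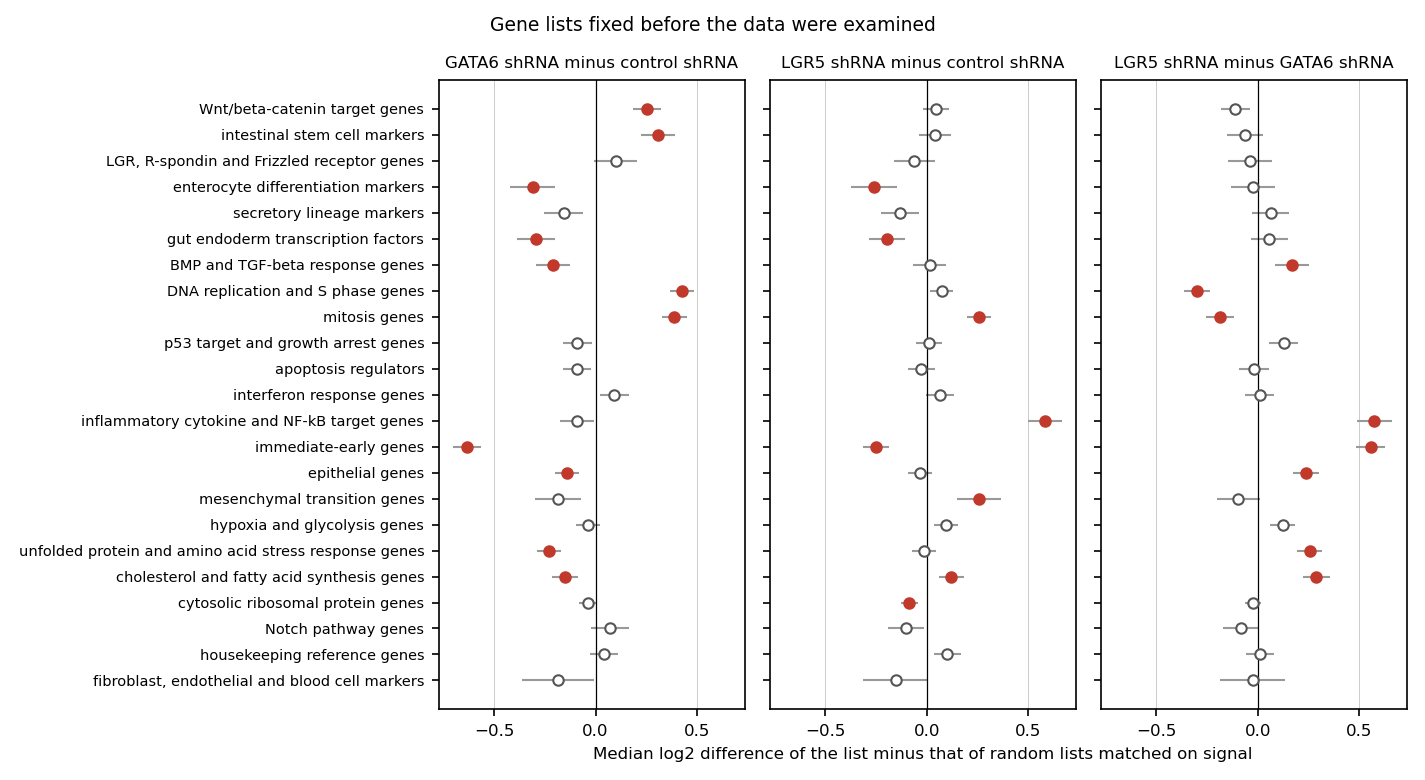
Median log2 difference of each gene list minus that of random lists matched on signal (x axis, log2) for 23 lists and the 3 comparisons; bars show the SD of random lists, and filled red points lie outside the central range of random lists. Immediate-early genes lay at -0.63 and DNA replication genes at 0.43 on the GATA6 shRNA array against the control, and the inflammatory list at 0.58 on the LGR5 shRNA array against the control.

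The comparison of the LGR5 shRNA and control arrays asked which transcripts differ when LGR5 is targeted. Of 14449 measured genes, 100 were at least 2-fold higher and 278 at least 2-fold lower on the LGR5 shRNA array. FAM20A, a secretory pathway pseudokinase, was highest at 7.59-fold, with a log2 difference of 2.92 ± 0.23. STS, which encodes steroid sulfatase, was 5.77-fold higher and PADI1, a peptidylarginine deiminase, 5.33-fold higher. ZBED2, a zinc finger transcription factor, was 5.61-fold higher with signals of 179 on the control array and 1378 on the LGR5 shRNA array. FAM50B was the brightest of the 10 highest genes, with signals of 7324 and 41804, a 4.15-fold difference. SLC66A1, PTPN5, KRTAP3-3 and NPB were 3.89 to 6.04-fold higher, and MKI67 was 4.34-fold higher. Among the lowest were HBD, IGKV1-5, ACKR5, OR10H3, OTOS, SYT9 and BNIP3, which were 8.25 to 13.97-fold lower and were also at least 4.73-fold lower on the GATA6 shRNA array. GDF9, an oocyte growth factor, was 11.0-fold lower and TMEM200C 8.54-fold lower. Both were also lower on the GATA6 shRNA array than on the control array, with log2 differences of -2.15 and -1.40. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was 13.4-fold lower, while its log2 difference between the GATA6 shRNA and control arrays was -0.57 ± 0.18. Bounds of at least 2-fold were found for 13 genes in the higher direction, among them at least 4.02-fold for MYH15, 3.24-fold for HSD11B1, 2.82-fold for SELENOV and 2.59-fold for CLDN22. In the lower direction 180 genes had such a bound, led by TBX21 at 67.3-fold and KRT77 at 50.1-fold, then GPR174 at 16.5-fold, RAG2 at 15.8-fold and WDR64 at 15.3-fold, all on the control-only side described above.

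The list of inflammatory cytokine and NF-kB target genes had the largest shift, 0.58, although only IL1A among 24 measured members reached 2-fold. IL1A was 2.12-fold higher by a dim probe, and its log2 difference was -0.15 after normexp background correction. Mitosis genes were shifted by 0.26, and DNA replication genes, at 0.07, lay inside the range of random lists. Immediate-early genes were shifted by -0.25, with EGR1 2.37-fold lower, and the short-lived transcripts by -0.16. Enterocyte markers were shifted by -0.26, with ALPI 2.02-fold lower, and gut endoderm transcription factors by -0.20. Mesenchymal transition genes were shifted by 0.26, cholesterol and fatty acid synthesis genes by 0.12 and ribosomal protein genes by -0.09; all 3, and the endoderm list, lost their place outside the range under at least 1 alternative. The ribosomal shift was 0.00 after quantile normalization. Wnt/beta-catenin targets, at 0.05, and intestinal stem cell markers, at 0.04, lay inside the range, as did markers of fibroblasts, endothelial and blood cells at -0.15. The 15 lists inside the range had shifts between -0.15 and 0.10. Among single members of other lists, MUC5B was 2.04-fold lower, PDGFRA 2.10-fold lower, CLDN1 2.28-fold higher and IFI44 2.23-fold higher, and the log2 difference of IFI44 was -0.02 after normexp background correction. The split of higher and lower genes depended on the scaling: 100 higher and 278 lower genes became 150 and 212 with median scaling, 199 and 155 after quantile normalization, 132 and 225 with local medians subtracted, and 1631 and 58 with spike-in scaling, which placed the median of all genes at 0.61. Above a signal of 100 on both arrays, 39 genes were higher and 62 lower. After normexp background correction 9 named genes were less than 2-fold different: STS (0.74), KRTAP3-3 (0.53), NPB (0.56), ALPI (-0.59), MUC5B (-0.87), PDGFRA (-0.60), TNFRSF10A (-0.96), and IL1A and IFI44 as given above. EGR1 was at -0.59 with spike-in scaling, and a second CLDN1 probe gave 0.80.

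The arrays of the shRNA-treated cells were then compared with each other, which leaves out the control array. Of 14433 measured genes, 205 were at least 2-fold higher and 330 at least 2-fold lower on the LGR5 shRNA array than on the GATA6 shRNA array. PADI1 was 15.6-fold, FAM20A 13.3-fold, SPINK4 10.53-fold and IL33 9.18-fold higher, and REG4 was 4.90-fold higher. PTPN5, SLC24A3, PRSS1, STS, UGT1A6 and IGFL2 were 6.61 to 9.88-fold higher. UGT1A6, a glucuronosyltransferase, shares exons with its family, so its assignment within the family is uncertain. HOXC10 was lowest at 19.4-fold, although its second probe gave a log2 difference of only -0.89, less than 2-fold. It was followed by CREB5 at 14.9-fold, MYH7B at 12.9-fold and GPNMB at 12.7-fold. CYP7A1, WDFY4, PSKH2, IL1B, BEX2 and PCP4 were 5.201 to 9.002-fold lower, of which PCP4, a calmodulin regulator, was bright, with signals of 11475 on the GATA6 shRNA array and 2781 on the LGR5 shRNA array. Bounds of at least 2-fold were found for 14 genes in the higher direction, the largest for MMP1, a collagenase, at 7.499-fold, then MYH15 at 3.99-fold, HSD11B1 at 3.22-fold, KRT6C at 2.88-fold and BPIFB3 at 2.55-fold. In the lower direction 93 genes had such a bound, led by FNDC9 at 26.6-fold, HTR1E at 26.5-fold, SLC26A7 at 12.6-fold, RPRML at 9.20-fold and ADAMTS4 at 9.18-fold. Other probes of HTR1E, SLC26A7 and ADAMTS4 were not well above background on either of these arrays.

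Between these arrays, inflammatory genes were shifted by 0.57 and immediate-early genes by 0.56. CSF2 was 3.77-fold and BIRC3 3.05-fold higher on the LGR5 shRNA array, while CCL2 was 4.44-fold lower. DUSP5, a phosphatase of ERK, was 4.28-fold higher, EGR3 2.45-fold, FOS 2.37-fold and FOSL1 2.24-fold. DNA replication genes were shifted by -0.30 and mitosis genes by -0.19. Epithelial genes were shifted by 0.24, with CLDN1 3.34-fold higher, unfolded protein genes by 0.26, cholesterol and fatty acid synthesis genes by 0.29 and BMP and TGF-beta response genes by 0.17, the last of which lay inside the range under 3 of 10 alternatives. Short-lived transcripts were shifted by 0.27. The remaining 15 lists lay inside the range, with shifts between -0.11 and 0.13. Among them were enterocyte markers (-0.03) and gut endoderm transcription factors (0.06), both lower on either shRNA array than on the control array. Their shifts against the control therefore cannot be told apart from an error of that shared array. Wnt/beta-catenin targets (-0.11) and intestinal stem cell markers (-0.06) were also inside. Of the members of these 15 lists, APCDD1 was 3.69-fold lower, SPDEF, a goblet cell transcription factor, 2.73-fold lower, LGALS4 2.76-fold higher, MMP7 2.94-fold higher and PLAUR 3.11-fold higher. The split of 205 higher and 330 lower genes became 267 and 257 with median scaling, 246 and 231 after quantile normalization and 810 and 108 with spike-in scaling, which placed the median of all genes at 0.37. After normexp background correction the genes less than 2-fold different included STS (0.93), CCL2 (-0.73), EGR3 (0.68), FOSL1 (0.9995), BMP7 (-0.59), LCT (-0.45), LRIG1 (-0.63) and SPINK1 (-0.83). SLC24A3 was at 0.54 after quantile normalization, and other probes gave 0.37 for SLC24A3, 0.84 for CLDN1 and 0.91 for FOSL1.

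The differences of both shRNA arrays from the control were set against each other across 14320 genes, which are not independent replicates. Pearson's r was 0.48 and Spearman's rho 0.45. Because both differences contain the same control array, unchanged arrays simulated with the spot error alone gave r of 0.59 and rho of 0.53. The covariance was 0.0893, against 0.0108 in the simulation. Genes at least 2-fold higher on both shRNA arrays numbered 36, where independent lists would share 2.13, and genes lower on both numbered 95, where independent lists would share 4.66. The simulated arrays shared 0.05 higher and 0 lower genes on average over 20 runs. The single control array could not be split, and part or all of the excess over independent lists may come from it, since the simulation leaves out other errors of that array. Genes in opposite directions numbered 5, with 5.69 for independent lists, and 2, with 1.75.

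**Figure D3:**
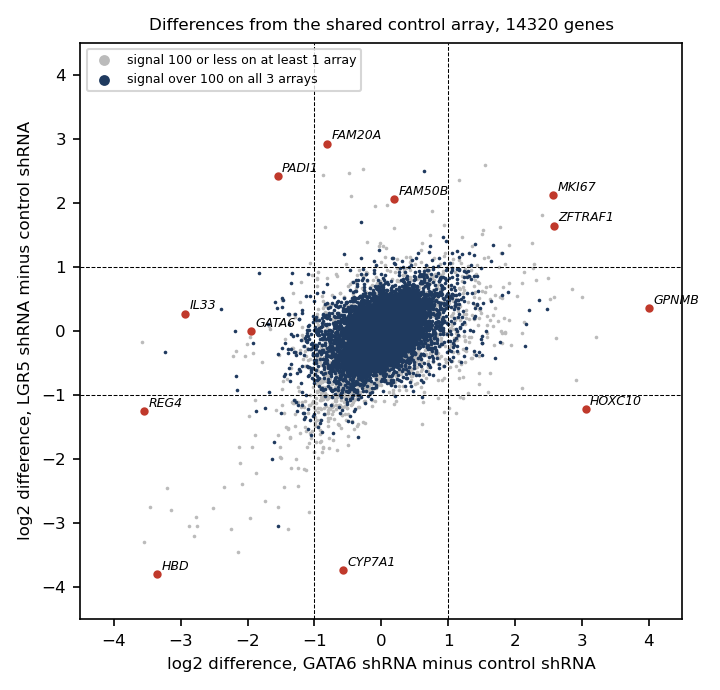
Log2 difference of the GATA6 shRNA array from the control array (x axis) against that of the LGR5 shRNA array (y axis) for 14320 genes, 1 point per gene; dark points had a signal over 100 on all 3 arrays, dashed lines mark 2-fold and red points are named genes. Most genes 2-fold lower on both arrays are dim, while GATA6 lies at -1.95 and -0.005.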

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

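Probes without a gene name took no part in the comparisons, and some of them were above or below the control array. On the GATA6 shRNA array, 206 of 8178 such probes measured on both arrays were at least 2-fold higher than on the control array and 280 were at least 2-fold lower. On the LGR5 shRNA array, 64 of 8236 were higher and 644 lower. Among named genes in that comparison, each by its brightest probe, 100 of 14449 were higher and 278 lower, a smaller share of lower calls. No explanation was tested for the unnamed probes on their own, and other scalings were not applied to them.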

How the results depend on the processing

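No paired analysis was possible because there was 1 array per group. The filters on signal over 100 and without genes seen on the control array alone were chosen after the data were seen. Most 2-fold calls were of dim probes, so the counts depend on the treatment of background; the cause was not tested beyond this. Counts are given as higher and lower for GATA6 shRNA minus control, LGR5 shRNA minus control and LGR5 minus GATA6 shRNA (309 and 262, 100 and 278, 205 and 330 as reported). They were 99 and 121, 28 and 85, 104 and 125 with normexp; 529 and 146, 1631 and 58, 810 and 108 with spike-in scaling; 590 and 894, 269 and 1113, 443 and 837 without the filter on dim probes. They were 56 and 82, 16 and 20, 75 and 46 above the median signal; 130 and 129, 39 and 62, 112 and 127 at a signal over 100. They were 983 and 1010, 525 and 1201, 737 and 1217 at 1.5-fold, and 71 and 56, 21 and 66, 56 and 79 at 3-fold. Quantile normalization gave 199 and 155 for LGR5 shRNA minus control. The other settings kept each count within 1.5 times the reported one, and without control-only genes the lower counts were 244, 259 and 329.

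The GATA6 log2 difference was -1.73 (GATA6 shRNA minus control), 0.65 (LGR5 shRNA minus control) and 2.38 (LGR5 minus GATA6 shRNA) with spike-in scaling, 0.092 and 2.04 for the last 2 with median scaling, and 2.03 for the last with local medians subtracted. The log2 bound for LGR5 against the control, -0.95 (GATA6 shRNA) and -1.15 (LGR5 shRNA) as reported, was -0.31 and -0.61 with normexp, and for the LGR5 shRNA array -0.69 after quantile normalization and -0.50 with spike-in scaling. The deposited table, which is centred, and the settings that change the filter or average probes gave no such bound. LGR5 was given as a bound against the control, and with no value between the shRNA arrays, because of its background calls, after differences computed without regard to them had been seen. The correlation of 0.48 was 0.45 with normexp, 0.50 after quantile normalization, 0.57 without the filter, 0.42 above the median signal and 0.46 without control-only genes. Of the 44, 29 and 46 named genes that were measured and at least 2-fold different in the comparisons, 11, 12 and 13 were less than 2-fold different under at least 1 alternative, most often normexp (7, 9 and 9). Of 27 list shifts outside the range, 21 stayed outside in the same direction under all 10 alternatives. Median scaling, spike-in scaling and the deposited table move all genes of a comparison alike. They leave a shift against random lists in place by construction, so they add no support. The ribosomal protein shift for LGR5 shRNA minus control changed sign, to 0.00366, after quantile normalization. BMP7 (-0.21) and TNF (-0.12) changed sign with another probe for GATA6 shRNA minus control, and IFI44 (-0.018) and IL1A (-0.15) with normexp for LGR5 shRNA minus control; the cause was not tested.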

Other observations

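The tests of a control-array error, of signal-dependent scaling and of ERK output, the lists of short-lived, ERK and blood cell transcripts and the set of bright genes with its counts under other scalings were chosen only after the result was seen. How far a value had to clear its bound was also revised after the values were known for the tests of a damaged patch, blood cell RNA and chromosome copies, and what each verdict rests on is stated.

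Among genes with a signal over 1000 on both arrays, a set chosen after seeing the data, 31 were at least 2-fold higher and 49 at least 2-fold lower on the GATA6 shRNA array than on the control array, and 75 and 17 with spike-in scaling. MYB, a transcription factor of intestinal progenitors, was 2.51-fold higher, with a signal of 15626 against 5701. TGFB2 was 2.66-fold, LTB 2.72-fold, IDH2 2.96-fold and CFTR, the epithelial chloride channel, 2.13-fold higher. PRSS2 and PRSS3, close relatives of PRSS1, were 3.76-fold and 2.79-fold lower, KLK7, a serine protease, 3.24-fold lower and ERRFI1, an inhibitor of EGFR, 2.62-fold lower. MAT2A, which makes S-adenosylmethionine, was 3.04-fold lower on the GATA6 shRNA array and 3.34-fold lower on the LGR5 shRNA array. On the LGR5 shRNA array 9 such genes were higher and 17 lower, among them SAA1 2.63-fold and IRS1 2.49-fold higher, and CCDC28A 3.17-fold and WTAP 2.45-fold lower. These counts depended on the scaling: they were 14 and 12 with median scaling and 524 and 2 with spike-in scaling, under which MAT2A (-1.08) and CCDC28A (-1.01) were the 2 lower genes and WTAP was at -0.63 on the log2 scale.

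The lower immediate-early genes and higher replication genes on the GATA6 shRNA array were weighed against 4 explanations. An error of the control array alone is argued against by the immediate-early shift of 0.557 ± 0.071 (SD of random lists) and the replication shift of -0.30 ± 0.06 between the LGR5 and GATA6 shRNA arrays. Signal-dependent scaling would also move random lists matched on signal, so a shift against such lists argues against it. The immediate-early shift of -0.569 ± 0.068 that remained after quantile normalization adds little, because that matching had already been made. Loss of short-lived transcripts, for example from a difference in harvest, stays open as a candidate explanation: 32 such transcripts were shifted by -0.501 ± 0.057. Many of these 32 also respond to growth factors and 10 belong to other fixed lists, so this test does not separate RNA handling from signalling. Against the control, lower ERK pathway output cannot be told apart from no change, because 10 output genes had a shift of -0.182 ± 0.113 with members on both sides of 0. DUSP4 and DUSP6 are also in the immediate-early list, and DUSP6 had already been seen. The list was shifted by 0.25 in LGR5 shRNA minus control (percentile 99.15) and by 0.46 in LGR5 minus GATA6 shRNA (percentile 99.95). Both lay outside the range. Because the first of these leaves out the GATA6 shRNA array, the second cannot be assigned to that array alone.

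The excess of signal on the control array alone was weighed next, and no biological explanation was tested for it. Of 43 other probes of the same genes that were well above background on that array, 28 were brighter there than on both other arrays, 6 of them at least 2-fold. Their median log2 difference from the brighter of those arrays was 0.20 over the 43. For genes of probes bright on the GATA6 shRNA array alone, 7 of 15 other probes were brighter there, with a median of -0.30. For the LGR5 shRNA array these values were 2 of 11 and -0.28. Bleed from bright neighbours is argued against, since 14.4% of these spots adjoined a spot brighter than 50000, against 10.2% to 18.1% in random sets. RNA of blood cells is argued against only narrowly: 8 of 16 blood cell transcripts had a median log2 difference of 0.184 (SD 0.742), which lies below the 1 such RNA would need by more than the SD but below the 0.5 written first by less, and S100A8 went the other way, with signals of 60.5, 15.3 and 19.8. A damaged patch stays open, because the median distance between neighbouring control-only spots, 6.40 spot steps, lay at the 10.8 percentile of random sets and above the 6.32 that bounds their lowest 5% by less than their SD. Isolated defects stay open too: 0.152% of repeated control-array spots stood 4-fold above their own probe, 4 of 2640 where 13.9 would match the control-only share, with 3 on the GATA6 shRNA and 4 on the LGR5 shRNA array and so no excess on the control array, but only 250 spots were dim enough to show a weak defect. On the GATA6 shRNA and LGR5 shRNA arrays such spots made up 0.114% and 0.152%. Probes at least 4-fold above both other arrays made up 0.176% and 0.098% there. Defects therefore also stay open for genes bright on either of these arrays alone, among them those given as bounds.

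Whether the populations differed in chromosome copies was tested as a hypothesis, with a negative outcome. The chromosome median farthest from that of all genes was -0.139, for 1067 genes of chromosome 19 in LGR5 shRNA minus control. It lay below the 0.2 set as the need by more than its spread of 0.0145, but inside the first bound of 0.15 by less than that spread, and a copy change in part of the cells is not excluded.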
